A study of Danio rerio with 10 samples.

How the data were processed

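The samples were 10 TransTag libraries of adult zebrafish tail fin DNA, 1 wild type and 9 transgenic. Per the labels' protocols, fin clips were lysed in 25 mM NaOH at 95 °C for 30 minutes, neutralised with 100 mM Tris, and purified on columns, and about 100 ng of DNA entered each library. The files the authors deposited hold 1 flanking sequence per line, with no header, no count column and no coordinates, and identical sequences repeat. Reads were therefore counted as lines. The deposited lengths ran from 0 to 94 bases, and flanks of 80 bases are taken as running to the end of the read. The anchor sequence, adapter trimming, read filters, aligner and genome build are not given in the sources used here. It follows that the shares below depend on an extraction step that could not be checked, and that the read's starting point is taken to be the first base after the Tol2 end.

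No genome was used here, so the placement of flanks on chromosomes that was planned before the data were examined was replaced by grouping flanks by sequence. A read placed in a family stands in for a read placed on the genome. The planned tests of gene overlap, of GC content against random genomic positions, of reads at the endogenous loci of the reporter elements (h2ax, h2az2a, mitfa, crestin, sox10, he1.1 and myl7), and of the leading junction's position were not run. The planned rule for naming genes, every gene at a called site or its nearest neighbours, gave no gene for the same reason.

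Residual Tn5 adapter (19 bases, at most 3 edits) was removed first. Flanks of 20 bases or more were kept, and their first 20 bases were compared with edlib 1.3.9.post1 in Python 3.11.15. Starting from the most frequent 20-mer over all libraries, a 20-mer within 4 edits of an earlier one joined its family, and otherwise founded a new family. This gave 40 families. The 11 that are named hold 162421 of 162487 reads, and the 29 others hold 66 reads, 22 of them having 1 read each and none more than 12. Consensus sequences were taken by majority per base in the library with most reads. Of the named families, 9 are flanks whose sequence is printed. Another matched the right end of Tol2 with 0 edits over 67 bases. The last, called the plasmid family, matched the sequence beside the pUC plasmid origin with 0 edits over 28 bases, after 20 bases of its own. That match was made on its consensus, taken in c635, and not on single reads of other libraries. On 10 simulated libraries with 12 known families and 44122 reads, family counts differed from the true counts by 0.029% of reads in sum. Exchanges of reads between families that cancel out are not seen by this measure.

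A family was called in a library at 10 reads or more and 1% of placed reads or more. Shares carry exact (Clopper-Pearson) 95% intervals from scipy 1.17.1, and a count of 0 is given as a limit of 3 counts. The number of end positions counts the lengths under 80 bases that at least 2 reads of a family had. It gives only a rough measure of separate tagmentation events, since reads are PCR copies. Events that end at the same position count once, and errors in length can add positions. Depth set the limit per library, from 0.0022% of placed reads in sox10:Kaede to 1.26% in the wild type.

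Batches were sought in the files. Reads that ran through the adapter into the index were sorted by their commonest index sequence, which gave 3 sets among the 9 transgenic libraries. Reads within 1 mismatch of it, of all such reads, were 2 of 2 in H2A.Z-mCherry, 82 of 84 in the compound line and 4891 of 4947 in sox10:Kaede (first set). They were 19 of 20 in c636, 9 of 9 in c787 and 7 of 7 in c403 (second set). They were 6 of 6 in c594, 3 of 3 in c635 and 64 of 68 in c591 (last set). The sets of H2A.Z-mCherry and c635 therefore rest on 2 and 3 reads. The wild-type library had no such read. Each line was put in 1 set, so line and set cannot be told apart. Alternatives were counting distinct sequences, a 30-base minimum, other call thresholds and another denominator, all chosen before the data were examined, and other edit limits, flanks from 8 bases and unremoved adapter, chosen after.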

Results

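TransTag libraries were made from adult zebrafish tail fin DNA to find where transgenes sit in the genome. Tol2 is a transposon whose ends are used to carry transgenes into zebrafish chromosomes. In this assay genomic DNA is cut and tagged by the Tn5 transposase, and fragments that contain the transgene's Tol2 end are amplified and read into the neighbouring DNA, called the flank here. The series held 10 libraries, 1 from a wild-type fish and 9 from transgenic fish. There was 1 library per line, so differences between lines have no replicate check. Intervals and detection limits given here cover counting error only, because PCR copies are not independent molecules.

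The lines differ in their reporters. Tg(h2ax:h2az2a-mCherry)mw3 carries a red fluorescent fusion of the histone variant H2A.Z. The compound line carries mitfa:mCherry and crestin:EGFP, reporters driven by elements of a melanocyte transcription factor gene and of a neural crest gene. Tg(sox10:Kaede)zf393 drives the photoconvertible protein Kaede from sox10, a neural crest transcription factor gene. The other 6 lines (c636, c787, c403, c594, c635 and c591) carry QUAS reporters, which respond to the transcription activator QF. Their products are membrane-targeted mApple, mApple, GFP, the calcium indicator GCaMP7a, GFP and membrane-targeted GFP, in that order. Some of their genotypes also name a second reporter: he1.1:mCherry in c636 and he1.1:CFP in c787, from a hatching gland gene, and cmlc:GFP in c635, from a heart gene.

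Depth differed widely. The wild-type library held 270 flanking sequences, and the c635 library 343. The c403, c787, c594, H2A.Z-mCherry and c636 libraries held 618, 1060, 1266, 1323 and 1596. The c591, compound and sox10:Kaede libraries held 9658, 16835 and 149234. After removal of residual adapter, between 50.2% (c594) and 93.9% (compound line) of the sequences in a library were 20 bases or longer. These 162487 reads were grouped by sequence into families, and 162421 of them fell into 11 families. Positions on chromosomes and the genes at each flank were not analysed here, because no genome sequence was used.

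The first question was what the assay returns from a fish without a transgene. A single family made up 234 of the 238 placed wild-type reads, a share of 98.3% (exact 95% interval 95.8 to 99.5%). Its consensus over 80 bases was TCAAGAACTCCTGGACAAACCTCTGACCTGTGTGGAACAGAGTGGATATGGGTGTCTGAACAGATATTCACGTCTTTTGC, with 46.2% GC. The other 4 wild-type reads were 2 of the sox10:Kaede flank, 1 of the H2A.Z-mCherry flank and 1 of Tol2 end sequence. The wild-type family was found in all 10 libraries and is called the shared flank below. It was the commonest family in 7 of them, and its share ranged from 11.8% of placed reads in H2A.Z-mCherry to 99.6% in sox10:Kaede. The leading family depended on flank length in 2 of the 7: with flanks from 8 bases the line's own flank led in c594, and with a 30-base minimum it led in c635 (50.8% against 43.5%). The wild-type library could miss a family of up to 1.26% of its placed reads, the limit that a count of 0 allows.

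**Figure D1:**
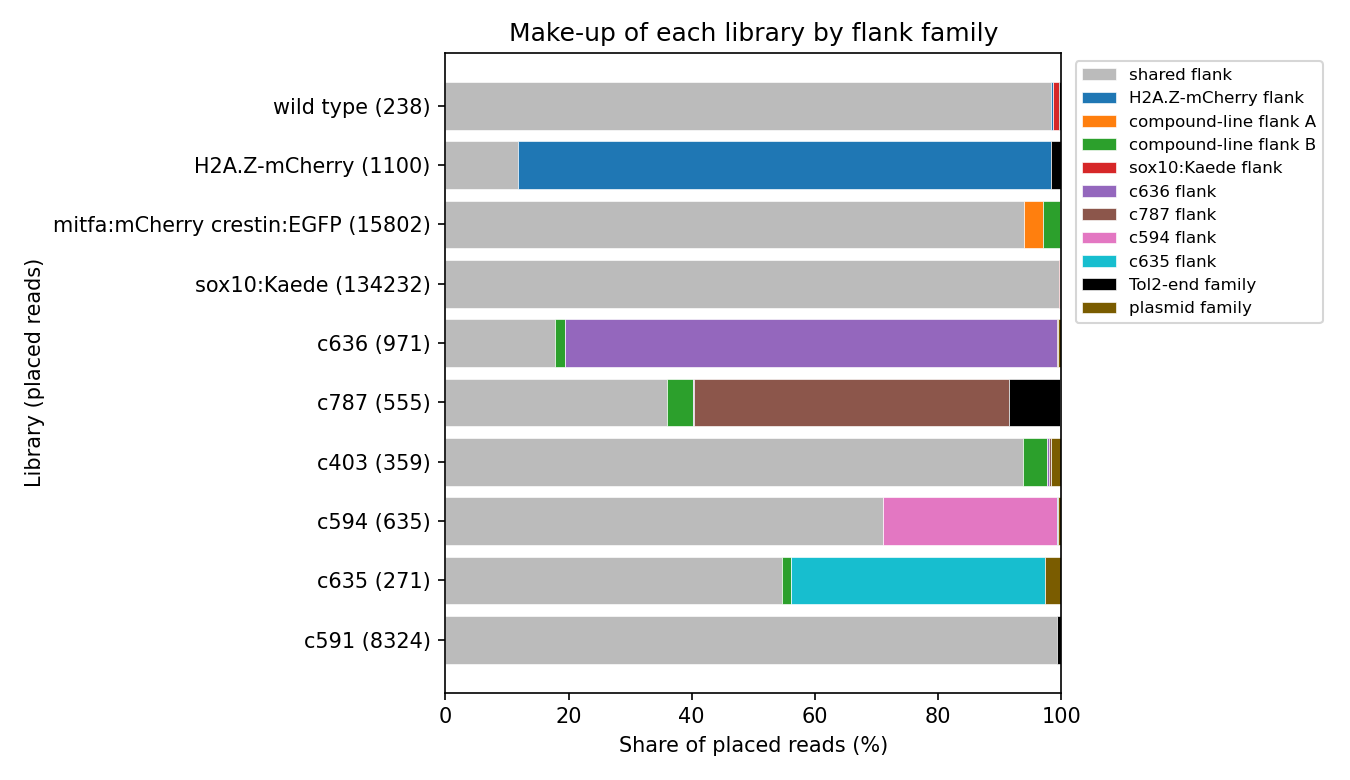
Share of placed reads (percent, horizontal axis) taken by each of 11 flank families in each of 10 libraries, with the number of placed reads beside each library name. The shared flank fills 98.3% of the wild-type bar, while another flank takes most of the H2A.Z-mCherry, c636 and c787 bars.

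The next question was whether each transgenic line showed a flank of its own. A family was called at 10 or more reads and at least 1% of a library's placed reads, which gave 1 to 4 families per library. Counting called families that had their highest read count in that library, and leaving out the shared flank, 5 transgenic libraries had 1 such flank, 1 had 2, and 3 had none.

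The H2A.Z-mCherry library was dominated by a single flank. It took 951 of 1100 placed reads, or 86.5% (84.3 to 88.4%), against 1 of 238 wild-type reads, or 0.42% (0.01 to 2.32%). Its consensus was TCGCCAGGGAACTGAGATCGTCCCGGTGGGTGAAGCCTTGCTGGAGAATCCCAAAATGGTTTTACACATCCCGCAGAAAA, which at 52.5% GC was the richest in GC of the 8 line flanks. Its reads stopped at 21 different positions short of 80 bases, each seen in at least 2 reads. Outside its own library this flank had 4 reads, 3 of them in the compound line.

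The compound line, whose label names mitfa:mCherry and crestin:EGFP, showed 2 flanks. Flank A, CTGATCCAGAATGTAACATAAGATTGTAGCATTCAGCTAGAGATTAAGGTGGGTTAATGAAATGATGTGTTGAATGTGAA, had 476 reads, or 3.01% of 15802 placed reads (2.75 to 3.29%). Flank B, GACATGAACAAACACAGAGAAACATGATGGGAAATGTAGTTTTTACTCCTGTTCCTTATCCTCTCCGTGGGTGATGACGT, had 446 reads, or 2.82% (2.57 to 3.09%). In flanks of 20 bases or more, a difference between their read counts was not resolved, with flank A at 51.6% of both together (48.3 to 54.9%, two-sided exact binomial p = 0.34 against equal shares in this library). That depended on the counting, since flank A had 47.0% (44.0 to 49.9%) with flanks from 8 bases and 62.0% (52.2 to 71.2%) by distinct sequences. Flank A ended at 15 positions and flank B at 16. The wild-type library had 0 reads of either, which allows up to 1.26% of its placed reads, a limit below both shares. Flank A was found in no other library, and flank B also appeared in the c636, c787, c403 and c635 libraries, with 16, 23, 14 and 4 reads. Flank B is assigned to the compound line by its read count. By share it was higher in c787 (4.14%) and c403 (3.90%). Neither flank met a 5% minimum, 1 of the other call thresholds tried. With each distinct sequence counted once, flank A had 12.7% and flank B 7.77% of the library. Which flank belongs to which reporter could not be read from the flanks alone.

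The sox10:Kaede library was the deepest and had the smallest share of a flank of its own. The flank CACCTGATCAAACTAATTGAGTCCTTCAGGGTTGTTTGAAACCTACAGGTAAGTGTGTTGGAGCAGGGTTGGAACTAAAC had 409 of 134232 placed reads, or 0.305% (0.276 to 0.336%). It ended at 19 positions and did not reach the 1% needed for a call. The wild-type library held 2 reads of it, or 0.84% (0.10 to 3.0%), so its share was not above the wild-type level, which rests on these 2 reads. With each distinct sequence counted once its share was 1.54%, which met the threshold. The 8 remaining libraries had 0 reads of it. In the compound line, c591 and H2A.Z-mCherry this allows up to 0.019%, 0.036% and 0.273% of placed reads, below the 0.305% here. In c636, c787, c403, c594 and c635 the limit lies above it.

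Among the QUAS lines, 4 of 6 showed 1 flank of their own. In c636 the flank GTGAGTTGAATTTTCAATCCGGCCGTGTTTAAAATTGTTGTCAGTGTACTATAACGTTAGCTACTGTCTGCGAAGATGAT took 776 of 971 placed reads, or 79.9% (77.3 to 82.4%), and ended at 18 positions. In c787 the flank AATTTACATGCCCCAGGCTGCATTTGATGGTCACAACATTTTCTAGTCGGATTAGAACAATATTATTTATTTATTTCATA took 284 of 555 reads, or 51.2% (46.9 to 55.4%), and ended at 12 positions. In c594 the flank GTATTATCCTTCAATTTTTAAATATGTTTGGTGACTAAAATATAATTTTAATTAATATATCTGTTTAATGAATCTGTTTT took 180 reads, or 28.3% of placed reads (24.9 to 32.0%), and ended at 11 positions. This flank had the lowest GC content of the line flanks, 17.5%. In c635 the flank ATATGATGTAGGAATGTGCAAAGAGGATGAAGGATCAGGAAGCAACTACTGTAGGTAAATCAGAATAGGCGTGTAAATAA took 112 of 271 reads, or 41.3% (35.4 to 47.4%), and ended at 5 positions. As a share of all flanking sequences, those too short to be placed included in the total, the c636, c787 and c594 flanks had 48.6%, 26.8% and 14.2%. These are lower limits, since shorter reads of these flanks count only in the total. With flanks from 8 bases the c594 flank had 52.9%, more than the shared flank there (46.8%). None of these 4 flanks had a read in the wild-type library, and each had at most 2 reads in any other library.

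With flanks assigned to the library with most reads, the c403 and c591 libraries showed no flank of their own. In c403 the shared flank took 337 of 359 placed reads, or 93.9% (90.9 to 96.1%). Flanks under 20 bases, which were not placed, made up 41.9% of c403. Shared-flank reads of 20 bases or more made up 54.5% of all its flanking sequences. That is a lower limit, since shorter reads of the shared flank count only in the total. With flanks from 8 bases its share of placed reads was 95.6%. The next family there was compound-line flank B with 14 reads, followed by 6 reads of the plasmid family. Flank B, at 3.90% of placed reads, was called in c403 but is assigned to the compound line by read count. In c591 the shared flank took 8267 of 8324 reads, or 99.3% (99.1 to 99.5%), followed by 54 reads of Tol2 end sequence. A count of 0 allows a flank of up to 0.836% of placed reads in c403 and up to 0.036% in c591. The limit in c403 lies above the share that the sox10:Kaede flank had in its library, and the limit in c591 lies below it. Whether these 2 transgenes have Tol2 ends is not given in the sources used here, and the limits apply only if they have the end that the assay reads.

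**Figure D2:**
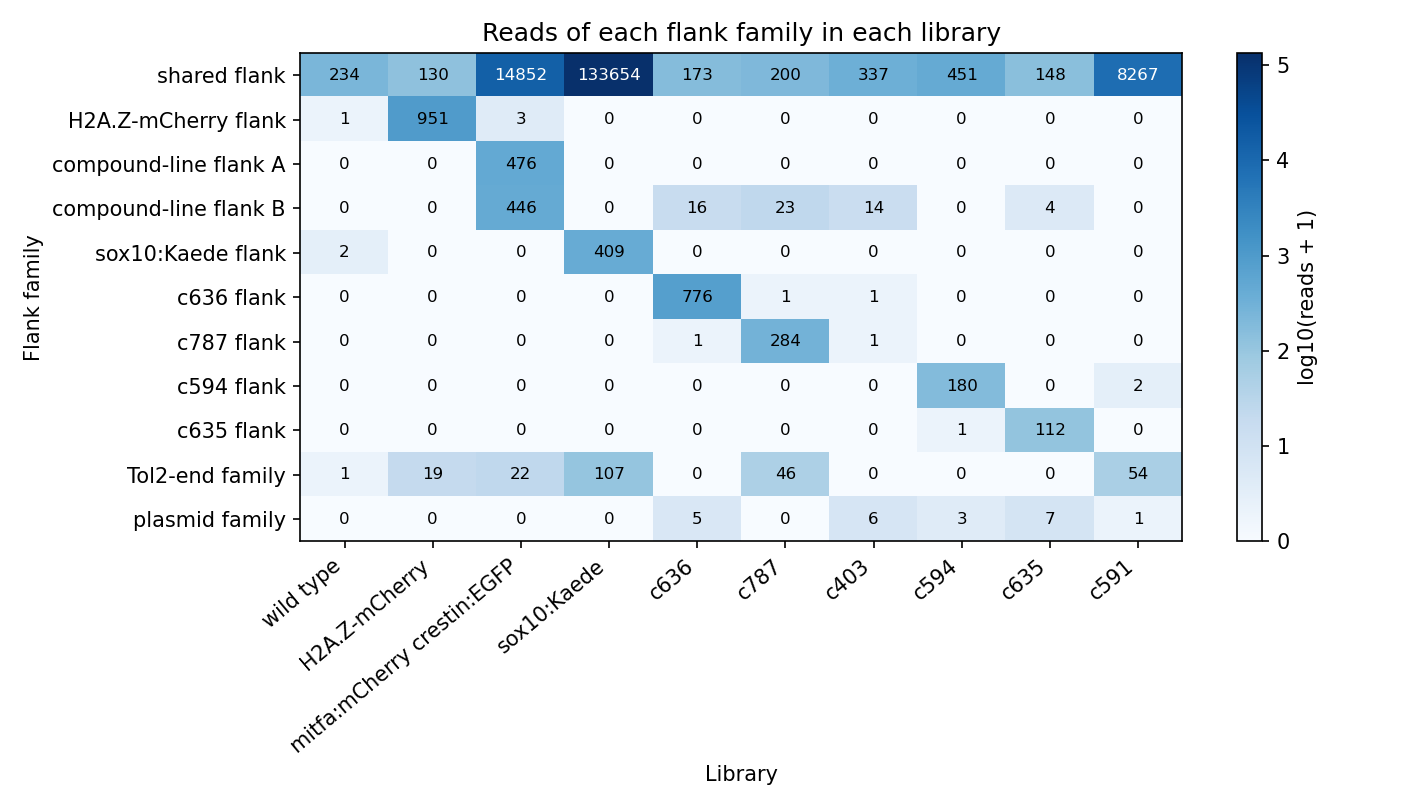
Reads of each of 11 flank families (rows) in each of 10 libraries (columns), with the count in each cell and shading by log10 of reads plus 1. Line flanks fill 1 cell each with at most 3 reads in any other library, except compound-line flank B, which has 4 to 23 reads in 4 QUAS libraries.

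The shared flank was then used as a reference within each library. The H2A.Z-mCherry flank had 7.32 reads per shared-flank read (6.08 to 8.86), and the c636 flank 4.49 (3.80 to 5.32). The c787 flank had 1.42 (1.18 to 1.71), the c635 flank 0.757 (0.587 to 0.974) and the c594 flank 0.399 (0.334 to 0.475). The compound-line flanks had 0.032 for A and 0.030 for B, and the sox10:Kaede flank 0.003. The ratios moved with the processing. The c594 flank had 1.13 with flanks from 8 bases, and the c635 flank 1.17 with a 30-base minimum. The c636 flank fell to 2.47 with flanks from 8 bases, and flanks A and B rose to 0.063 and 0.059 with a 30-base minimum. With distinct sequences counted once, H2A.Z-mCherry fell to 2.96, and flank A, flank B and sox10:Kaede rose to 0.162, 0.099 and 0.016. These ratios compare single libraries and amplification of different sequences, so they are not copy numbers.

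**Figure D3:**
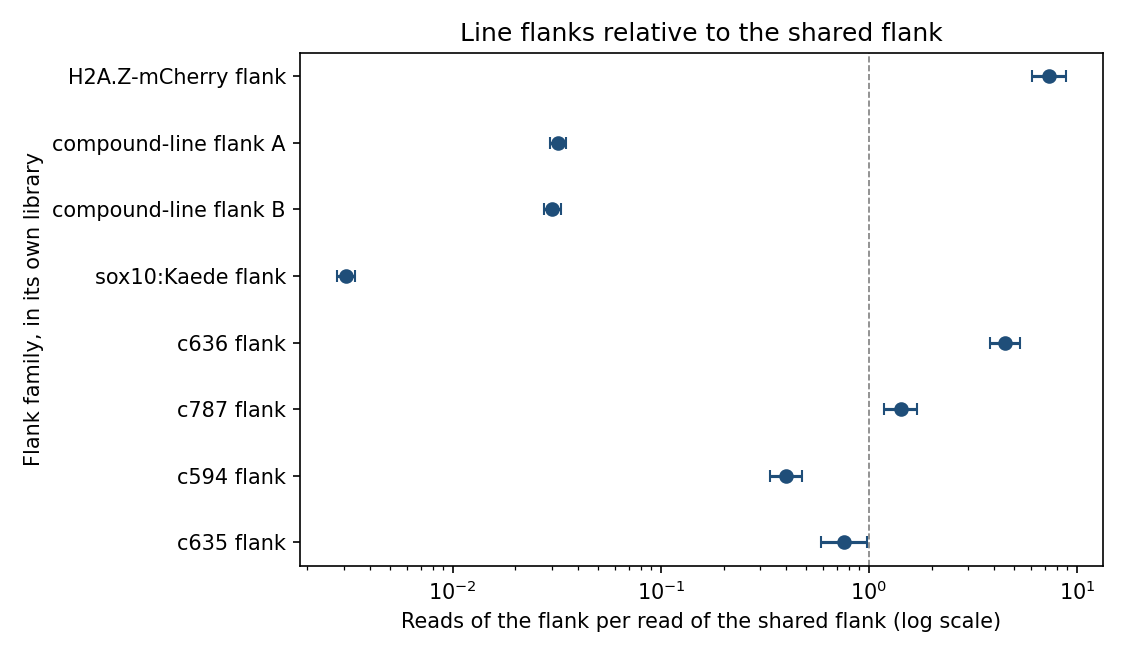
Reads of each line flank per read of the shared flank in the same library (log axis), with exact 95% intervals from counting error, for flanks of 20 bases or more with every read counted. The ratios run from 0.003 for the sox10:Kaede flank to 7.32 for the H2A.Z-mCherry flank, and the dashed line marks equal read counts.

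Tol2 duplicates 8 bases of the target when it inserts, so flanks read from the opposite ends of 1 insertion begin with reverse-complementary 8-mers. Among the 45 pairings of the 9 printed flanks, each with itself included, 0 met this with at most 1 edit. Which Tol2 end was read is not given, and if it was always the same end no pair could occur, so this 0 says nothing about how many insertions there are. The 8 line flanks began with TCGCCAGG, CTGATCCA, GACATGAA, CACCTGAT, GTGAGTTG, AATTTACA, GTATTATC and ATATGATG, in the order used above. A or T made up 38 of these 64 bases, or 59.4% (46.4 to 71.5%). GC content over 80 bases had a median of 38.2% among the line flanks. With no genome sequence used here, neither value was set against a genomic background.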

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

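All tests in this part were chosen after the counts were seen.

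Compound-line flank B appeared outside its own library, in data no comparison used. It took 4.14% of placed reads in c787 (2.64 to 6.15%) and 3.90% in c403 (2.15 to 6.46%). Both lie above the 1.26% that 0 wild-type reads allow. In c636 it took 1.65% (0.94 to 2.66%), an interval that spans that limit. By distinct sequences it was called in none of them, nor in c635. Its distinct sequences numbered 7 of 164 in c636, 2 of 72 in c787, 2 of 51 in c403 and 2 of 64 in c635. These counts were below the minimum number for a call. In c787 and c403 its reads had 1 length each, so they differ only by errors or variants. The missing calls therefore do not speak to its share. Reads passed on after amplification would bring flank A at its ratio to B, which predicts 60.8 reads of A beside the 57 reads of B in these 4 libraries, and 0 were found. An insertion carried by the c787 fish stays open: its 23 reads of flank B all ended at 1 position, against 3 or more in 10000 subsamples of as many c787-flank reads, but reads are PCR copies and 1 captured molecule would give this too. Whether a few molecules of compound-line DNA came in before amplification cannot be told: 4 molecules, 1 per library, would all be flank B with a probability of 0.055, but 2 of the 16 reads in c636 have other lengths, and 5 or 6 molecules would give 0.026 or 0.013. A source that carries flank B without flank A was not tested. Nor was an insertion carried by the c403 fish, whose 14 reads of flank B also all ended at 1 position.

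The shared flank in the other libraries could be material from the sox10:Kaede library, which holds 84.4% of its reads. That library also holds 134232 of all 162487 placed reads, so this share mostly follows from its depth. Reads passed on after amplification, as the sole source, are argued against: at the ratio in that library the compound line and c591 would hold 70.75 reads of the sox10:Kaede flank and the 5 other QUAS libraries 4.01, and both held 0. For the wild-type and H2A.Z-mCherry libraries together 1.11 reads were predicted and 2 were found, both in the wild type, so this source cannot be told apart from a sequence native to the wild-type fish. The compound line as the wild type's source after amplification is argued against in the same way, since 14.53 reads of its flanks were predicted and 0 found. Molecules carried over before amplification stay open, because reads are PCR copies and the ratio of molecules is not known. At the ratio of reads, 1 molecule per end position predicted 0.41 of the sox10:Kaede flank in the compound-line and QUAS libraries. It predicted 1.06 of the compound-line flanks in the wild type, and 0 reads were found in both cases. Ratios by distinct sequences were higher (0.016 for sox10:Kaede, 0.162 for flank A and 0.099 for flank B). They would predict more, so the values at the ratio of reads cannot decide.

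Tol2 end sequence took 8.29% of placed reads in c787 (6.13 to 10.9%), above the wild-type level of 0.42% (0.01 to 2.32%). It was also called in H2A.Z-mCherry with 19 reads (1.73%, 1.04 to 2.68%), an interval that overlaps the wild type's. All 46 reads in c787 and all 19 in H2A.Z-mCherry were 67 bases long, but so were 248 of the 249 reads of this family in 6 libraries. A length common to the libraries cannot tell copies of 1 molecule from several molecules. By distinct sequences the Tol2 end was called in neither library, but reads of 1 length differ only by errors or variants, so this does not speak to its share. The plasmid family took 1.67% of placed reads in c403 (6 reads, 0.62 to 3.60%) and 2.58% in c635 (7 reads, 1.04 to 5.25%). Neither was called, and both intervals reach below the 1.26% that 0 wild-type reads allow.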

How the results depend on the processing

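Of 205 values recomputed under 11 settings, 140 stayed within the main value's interval (shares) or within 1.5 times (counts of called families), and 65 moved. All 7 own flanks called in the main analysis were also called under the other settings that recompute calls, except with a 5% minimum, which kept 5 and lost both compound-line flanks. The leading family changed in c594 with flanks from 8 bases (own flank 52.9%, shared flank 46.8%) and in c635 with a 30-base minimum (own 50.8%, shared 43.5%). No paired analysis was possible because each line has 1 library. The alternatives of aligner, mapping quality, junction merging and clipping, windows around a site, gene classes and GC windows were not run, because they need a genome; the limit on end pairs within 100 bases needs one too.

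Called families moved as follows. Counting distinct sequences gave 2 in sox10:Kaede (main 1; its own flank was added), 2 in c787 (main 4) and 1 in c403 (main 2). A 30-base minimum gave 1 in c403 and 2 in c591 (main 1). A 5% minimum gave 1 in the compound line (main 3) and 1 in c403. No share minimum gave 4 in sox10:Kaede and 2 in c591. A minimum of 3 reads gave 4 in c635 (main 2). Leaving out families with more reads elsewhere gave 0 in the wild type (main 1), c403 and c591, and 1 in H2A.Z-mCherry (main 3), c636 (main 3), c787, c594 (main 2) and c635.

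Shares of the shared flank by distinct sequences were 93.8% in the wild type, 78.2% in the compound line, 97.7% in sox10:Kaede, 90.2% in c403, 63.5% in c594 and 98.4% in c591. With a 30-base minimum they were 88.8% in the compound line, 99.4% in sox10:Kaede, 59.9% in c594, 43.5% in c635 and 98.6% in c591. Shares over all flanking sequences were lower limits, since reads under 20 bases counted only in the total. They were 86.7% in the wild type, 88.2% in the compound line, 89.6% in sox10:Kaede and 54.5% in c403. They were 35.6% in c594, 43.1% in c635 and 85.6% in c591. With flanks from 8 bases they were 92.9% in the compound line, 46.8% in c594 and 99.1% in c591. With 2 edits they were 99.2% in sox10:Kaede and 99.1% in c591, and with adapter kept 99.0% in sox10:Kaede.

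Shares of own flanks by distinct sequences were 74.0% in H2A.Z-mCherry, 73.8% in c636, 33.3% in c594, 1.54% in sox10:Kaede, and 12.7% (A) and 7.77% (B) in the compound line. With a 30-base minimum they were 84.5% in c636, 57.2% in c787, 39.2% in c594, 50.8% in c635, 0.392% in sox10:Kaede, and 5.62% (A) and 5.27% (B) in the compound line. Over all flanking sequences the shares of own flanks were lower limits too, with reads under 20 bases only in the total. They were 71.9% in H2A.Z-mCherry, 48.6% in c636, 26.8% in c787, 14.2% in c594, 32.7% in c635 and 0.274% in sox10:Kaede. With flanks from 8 bases they were 67.4% in c636, 60.7% in c787, 52.9% in c594 and 3.66% for flank B in the compound line. Flanks under 20 bases made up 6.14% (compound line) to 49.8% (c594) of a library, which limits every share given here.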

Other observations

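All tests in this part were chosen after the counts were seen.

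The plasmid family was read only in QUAS libraries, counting reads of 20 bases or more. It had 5 reads in c636, 6 in c403, 3 in c594, 7 in c635 and 1 in c591, and 0 in c787 and in the 151372 placed reads of the 4 other libraries. Reads of 8 to 19 bases that match its start numbered 39 in c636 and 27 in c591. These reads end before the plasmid match, which begins after 20 bases, so they hold none of it. The reads of 20 bases or more in c636, c403 and c635 ended at 44, 46 and 48 bases, 1 length per library. Those in c594 ran to the end of the read. The Tol2 end family occurred in 6 libraries, and 248 of its 249 reads were 67 bases long, ending 3 bases before the Tol2 end.

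The shared flank often ended at the same positions in libraries of different lines. Lengths of 21 and 28 bases were among the 5 commonest under 80 bases in all 10 libraries, and lengths of 38 and 52 bases in 9. A length of 42 bases was common in 5 libraries. It made up 13.2% of shared-flank reads in the wild type, 13.2% in the compound line and 11.5% in sox10:Kaede. It made up 8.5% in H2A.Z-mCherry and 4.2% in c591, and had 0 reads in c787 and c403. The wild type was close to sox10:Kaede at the other lengths too: 21.4% and 20.3% at 21 bases, 7.7% and 7.1% at 28, 8.5% and 8.5% at 38, and 6.8% and 6.1% at 52. H2A.Z-mCherry had 26, 13, 9 and 13 of its 130 shared-flank reads at these 4 lengths, so sox10:Kaede is not the only library that resembles the wild type. Equal lengths do not tell shared cutting preference from material carried over, and carry-over into the wild type is not excluded.

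Line flanks that strayed into another transgenic library did so within an index set. Leaving out flank B and the wild type, 10 reads were found in 7 pairs of own and receiving library, and all 7 pairs lay in 1 index set. Of the 280 ways to form 3 sets of 3 libraries, only the real one gave 7, and no other gave more than 6 (exact permutation p = 0.0036, one-sided). With flank B included, 7 of 11 pairs lay in 1 set (exact permutation p = 0.0071, one-sided). Reads passed between libraries that carry the same index sequence would give this. Material carried over among libraries handled together would give it too if handling followed the sets, and the test cannot tell these apart. Flank B goes the other way, having been found in c636, c787, c403 and c635, none of which shares an index with the compound line.

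A variant of the shared flank, C2A (positions from the first base of the flank), was used to ask whether reads are copies of few molecules, counting reads of 16 bases or more, a minimum set after the lengths were seen. In c636, 26 of 30 variant reads were 16 bases long (86.7%), against 27.7% of unvaried reads, and in c403, 16 of 17 (94.1%), against 25.4%. Independent sequencing errors would spread variant reads over lengths as the unvaried reads are, which these shares argue against: in 100000 draws of as many unvaried reads, none had as large a share at any length (Monte Carlo exact multinomial p = 1e-05 in both, the smallest the draws can give). The same exact test in the 5 other libraries with variant reads gave p = 0.9 in sox10:Kaede (273 variant reads), 0.9 in the compound line (5), 0.8 in c591 (9), 0.1 in c635 (2) and 0.04 in c594 (3), uncorrected. A hypothesis is that the variant reads of 16 bases, 26 in c636 and 16 in c403, may be copies of 1 or a few altered molecules; the libraries share an index set, so reads passed between them are not excluded.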
